A study of Rattus norvegicus with 84 samples.

How the data were processed

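The series holds 84 libraries of total RNA from kidney, liver and gastrocnemius of male Sprague Dawley rats. Per the labels, each tissue has 10 libraries of 6-month and 10 of 24-month rats on vehicle and 8 of 24-month rats on RAD001. The labels give replicate numbers but do not state which libraries come from the same rat or that each comes from a separate one, so the p-values measure the spread between libraries.

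Per the submitters' processing notes, reads were aligned with STAR 2.4.5a to the rat genome rn5. The tool that summarised reads over genes is not given in the sources used here. The deposited values are a coverage signal: mean read coverage per base over the exons of a locus, multiplied by a factor per library. This unit was read from the values themselves. On short single-exon loci the value times the locus length, rounded to 10 bp, was a whole multiple of 1 step per library for 98.9% to 100% of the 69 to 204 loci tested per library. A product counted as whole within 2e-06 of its multiple plus 1e-06 at any of 3 lengths 10 bp apart, and the step was chosen from the same loci. The inverse of the step gives the relative depth of each library, which spanned 0.826 to 1.41, a 1.71-fold range. The number of reads per library is not given in the sources used here. At the lowest depth 1 covered step is the smallest difference a locus can show, so values near 0 carry little precision. The tables hold 17502 loci with 16997 unique symbols; 505 loci repeat a symbol and 140 carry joined symbols. No pair of libraries was identical, and the highest correlation of a pair was 0.996. The locus named LOC102723236 was identified as 7SL RNA from a RefSeq gene table of assembly GRCr8, used for names alone. Coordinates are those of the deposited tables (rn5).

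The design written before the data were examined assumed read counts. Since the unit is a coverage signal, limma was used in place of tests for counts. Within each tissue, loci with a value of at least 0.1 in at least 8 libraries were kept. Libraries were scaled by the trimmed mean of log ratios, with 30% trimmed on each side, and log2(scaled value + 0.1) was fitted with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3, with 1 mean per group over 28 libraries and 25 residual degrees of freedom. The contrasts were aged vehicle against young vehicle, RAD001 against aged vehicle and RAD001 against young vehicle. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a tissue and contrast were called. Tables were handled with the R package data.table (version 1.17.8), Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

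Gene lists (37 over all tissues) were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 and, as an alternative, at a correlation estimated from the residuals. Lists with fewer than 3 measured members were left out. Counter-regulated genes are those called in both the age and the RAD001 contrast with opposite signs. Because both contrasts share the aged vehicle libraries, the relation was also computed in simulated groups without change and with these libraries divided between the contrasts. Differences between tissues were tested by interaction terms in joint fits.

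The rule for named genes was also fixed then. It takes the 5 largest rises and the 5 largest falls among called genes with a mean of at least 1 and a proper name. For up to 10 called lists it takes the 2 members with the smallest p in the list's direction. It adds a set of fixed genes per tissue and up to 6 counter-regulated genes per direction with the smallest larger p. Other names, such as members that went against their list, were chosen after their values were seen. Some genes that the rule names are not reported here. Among the fixed genes, Cdkn2a was below the filter in kidney and liver, and Myc and Gdf15 were below it in gastrocnemius.

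The fits were tested on simulated data made from the real residuals, shuffled per gene, which breaks the correlation between genes. Of 50 genes changed 1.25-fold, the kidney age fit recovered 34 and the kidney RAD001 fit 37, the liver fits 31 and 26 and the gastrocnemius fits 35 and 42. At 2-fold the counts were 49, 49, 50, 50, 50 and 50 in the same order. False calls numbered 6 and 9 among 10247 unchanged genes in kidney, 14 and 9 among 8791 in liver and 11 and 13 among 8636 in gastrocnemius.

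The alternatives were median-of-ratios and upper-quartile scaling, no filter, a value of at least 1 in at least 8 libraries, the replicate number as a block, only the 2 groups compared, an adjusted p under 0.01, a change of at least 1.5-fold, and each library left out in turn. Added after seeing the data were sample quality weights (with statmod 1.5.0 installed), pseudocounts of 0.01 and 0.5, the values as deposited without scaling, a term for odd or even replicate numbers, the log2 7SL level as a covariate, and liver without the libraries whose 7SL value was under 18000. A count-based test written into the design was not run, since the values are not counts. Genes with near-identical copies, such as Rn5-8s, the Sult2a, Akr1b7 and Cyp2c families, RT1 genes, Myh6 and Myh7, Gsta1 and Gstm2, and ribosomal protein genes with pseudogenes, may share reads, and their values are uncertain.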

Results

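RNA was sequenced from kidney, liver and gastrocnemius muscle of male Sprague Dawley rats, an outbred laboratory strain, in 84 libraries. Each tissue had 10 libraries from rats of 6 months on vehicle (young), 10 from rats of 24 months on vehicle (aged) and 8 from rats of 24 months given RAD001 once a week for 6 weeks (treated aged). RAD001 is everolimus, a rapalog that inhibits mTORC1, the kinase complex that drives ribosome production and protein synthesis. Levels below are mean read coverage per base, scaled between libraries and given as mean ± SD, and log2 changes are on the scale log2(scaled coverage + 0.1), which understates changes of low genes. Adjusted p-values are those of limma with Benjamini-Hochberg adjustment over all genes tested in a tissue.

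In kidney the median relative sequencing depth was 1.10 in the young, 1.13 in the aged and 0.969 in the treated aged group. The corresponding medians were 0.960, 0.985 and 1.13 in liver and 0.931, 0.933 and 0.913 in gastrocnemius. The libraries held 11697 to 13767 loci with a value above 0. Abundant non-coding RNAs, whose values in this paragraph are as deposited without scaling, also differed between groups. 7SL RNA, the RNA of the signal recognition particle, stood in kidney at 25407 ± 1817 (SD, n = 10) in the young, 25258 ± 2573 (SD, n = 10) in the aged and 33651 ± 3931 (SD, n = 8) in the treated aged group, as deposited. The ribosomal RNA precursor Rn45s stood at 423 ± 45.3 (SD, n = 10), 430 ± 67.2 (SD, n = 10) and 232 ± 27.4 (SD, n = 8) in the same kidney groups. In liver Rn45s stood at 323 ± 93.8 (SD, n = 10), 334 ± 75.5 (SD, n = 10) and 417 ± 39.7 (SD, n = 8), and in gastrocnemius at 334 ± 67.3 (SD, n = 10), 247 ± 37.2 (SD, n = 10) and 280 ± 16.1 (SD, n = 8). In liver, 7SL had a wide spread in the young (18647 ± 5541, SD, n = 10) and aged (18795 ± 4581, SD, n = 10) groups and a narrow one in the treated aged group (22220 ± 917, SD, n = 8). In gastrocnemius it stood at 18865 ± 2493 (SD, n = 10), 18548 ± 2242 (SD, n = 10) and 17262 ± 1830 (SD, n = 8).

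The comparison of aged with young kidneys asked which transcripts change with age in the organ whose age-related pathology the series is about. Most measured markers of tubular injury were higher in aged kidneys. Lcn2 (chromosome 3, 16763059 to 16766404, rn5), the secreted iron-siderophore carrier NGAL of stressed tubules, rose from 0.196 ± 0.0744 to 3.0 ± 2.4 (SD, n = 10 each; log2 change 2.92, adjusted p = 1.95e-06). Havcr1 (chromosome 10, 31644784 to 31668189), which encodes kidney injury molecule KIM-1, rose from 0.0766 ± 0.0466 (SD, n = 10) to 1.64 ± 1.45 (SD, n = 10), a log2 change of 2.76 (SE 0.395, adjusted p = 3.69e-06). Spp1, the phosphoprotein osteopontin, rose from 20.3 ± 5.54 to 183 ± 127 (SD, n = 10 each). Cdkn1a, the p53 target p21, rose from 0.170 ± 0.0356 to 0.447 ± 0.0599 (SD, n = 10 each; adjusted p = 2.96e-10). Many transcripts of proximal tubule function fell.

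Of 25 measured genes of the tubular injury list, 21 rose over all genes tested and 21 adjusted over the list alone, among them Lgals3, the lectin galectin-3 (log2 change 1.39, adjusted p = 3.35e-07). The list was called by limma's camera at a preset correlation (adjusted p = 5.77e-10) and not with an estimated one (adjusted p = 0.184 with an estimated correlation). Tff3, a secreted mucosal repair peptide of the same list, fell from 106 ± 32.5 (SD, n = 10) to 34.3 ± 16.9 (SD, n = 10), a log2 change of -1.75. In the proximal tubule list 23 of 30 genes fell (24 adjusted over the list alone; adjusted p = 0.213 with an estimated correlation). Slc22a12, the urate transporter URAT1, fell from 17.9 ± 2.80 to 8.76 ± 2.43 (SD, n = 10 each; log2 change -1.05), and Ggt1, a brush border enzyme of glutathione breakdown, had a log2 change of -0.88 (adjusted p = 1.03e-06). Slco1a1, an organic anion transporter (log2 change -2.14), Gucy1b2, a soluble guanylate cyclase subunit (-1.55), Rgn, the calcium-binding protein regucalcin (-1.51), and Dhrs7, a short-chain dehydrogenase (from 24.5 ± 5.39 to 9.86 ± 4.78, SD, n = 10 each), had with Tff3 the 5 deepest falls among called genes with a mean of at least 1 and a proper name.

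Many immune cell transcripts rose with age in kidney. All 18 measured macrophage markers rose (18 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation), including the mannose receptor Mrc1, from 0.0808 ± 0.0166 to 0.385 ± 0.170 (SD, n = 10 each), and the lipid-sensing receptor Trem2 (log2 change 1.42, adjusted p = 3.40e-07). Among T cell markers 13 of 14 rose, also 13 adjusted over the list alone (adjusted p = 0.177 with an estimated correlation), with Cd4 at a log2 change of 0.84 and the T cell receptor chain Cd3d at 1.13. MHC class II genes rose in 9 of 9 cases (9 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation), and RT1-DMb and RT1-DMa, which load peptides onto class II molecules, had log2 changes of 0.48 and 0.70. Complement genes rose in 10 of 13 cases (10 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation). Of 32 interferon response genes, 28 rose (29 adjusted over the list alone; adjusted p = 0.259 with an estimated correlation), including the immunoproteasome subunit Psmb8 (log2 change 1.08) and the chemokine Cxcl11 (0.68). Ccl21, a chemokine that draws lymphocytes and dendritic cells, rose from 1.11 ± 0.240 to 4.58 ± 2.06 (SD, n = 10 each; adjusted p = 4.60e-07). Ubd (chromosome 20, 3917781 to 3919728), the interferon-inducible ubiquitin-like protein FAT10, rose by 1.92 (SE 0.516, adjusted p = 0.00335), and Guca2a, a natriuretic peptide, by 1.55 (SE 0.301).

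Among matrix genes, 24 of 29 genes of the fibrosis list rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.184 with an estimated correlation). Ctgf, a matricellular growth factor partner, rose from 0.837 ± 0.136 to 1.77 ± 0.266 (SD, n = 10 each; adjusted p = 5.30e-09), and the fibrillar collagen Col3a1 by 0.77 on the log2 scale (adjusted p = 0.000185). Tgfbi, an adhesion protein of the matrix, fell (log2 change -0.54, adjusted p = 0.000278). All 12 measured immediate early genes rose (12 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation), and the proliferation list had 6 of 11 raised (6 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation). Cytosolic ribosomal protein genes rose in 30 of 43 cases (33 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation), with Rps20 at 0.33 and Rpl3 at 0.34 on the log2 scale.

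Many genes of mitochondrial energy production fell. In oxidative phosphorylation 36 of 42 genes fell (41 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation), among them Sdha, the flavoprotein of complex II, from 25.5 ± 1.19 to 20.1 ± 2.39 (SD, n = 10 each). In fatty acid oxidation 20 of 24 genes fell (20 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation), with the trifunctional protein subunit Hadha at -0.59 (adjusted p = 2.53e-10) and the peroxisomal enzyme Ehhadh at -0.90. Fatty acid synthesis had 8 of 14 genes lowered (8 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation) and sterol synthesis 6 of 22 (4 adjusted over the list alone; adjusted p = 0.345 with an estimated correlation). Of the other fixed genes, Myc rose by 0.78 (adjusted p = 1.40e-06). The log2 changes of Mtor (-0.12, adjusted p = 0.161), Gdf15 (0.44, adjusted p = 0.102), Kl, the anti-ageing hormone klotho (-0.28, adjusted p = 0.0671), and Nphs1, the podocyte protein nephrin (-0.21, adjusted p = 0.111), did not pass the test.

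In all, 2174 of 10447 genes tested in kidney rose and 2318 fell with age. With the factors set at the upper quartile of each library, 64.6% of the called genes rose, against 48.4% with the trimmed mean, and the values as deposited gave 62.8%. Of 25 lists tested, 15 were called by camera at the preset correlation, and the smallest adjusted p with an estimated correlation was 0.177. With a value of at least 1 in 8 libraries sterol synthesis (adjusted p = 0.503) and proliferation (adjusted p = 0.130) were no longer called at the preset correlation. The lists not called were ribosome biogenesis, glycolysis, ATF4 targets, lysosome and autophagy, circadian clock, erythroid, adipocyte, podocyte, distal tubule and collecting duct markers.

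**Figure D1:**
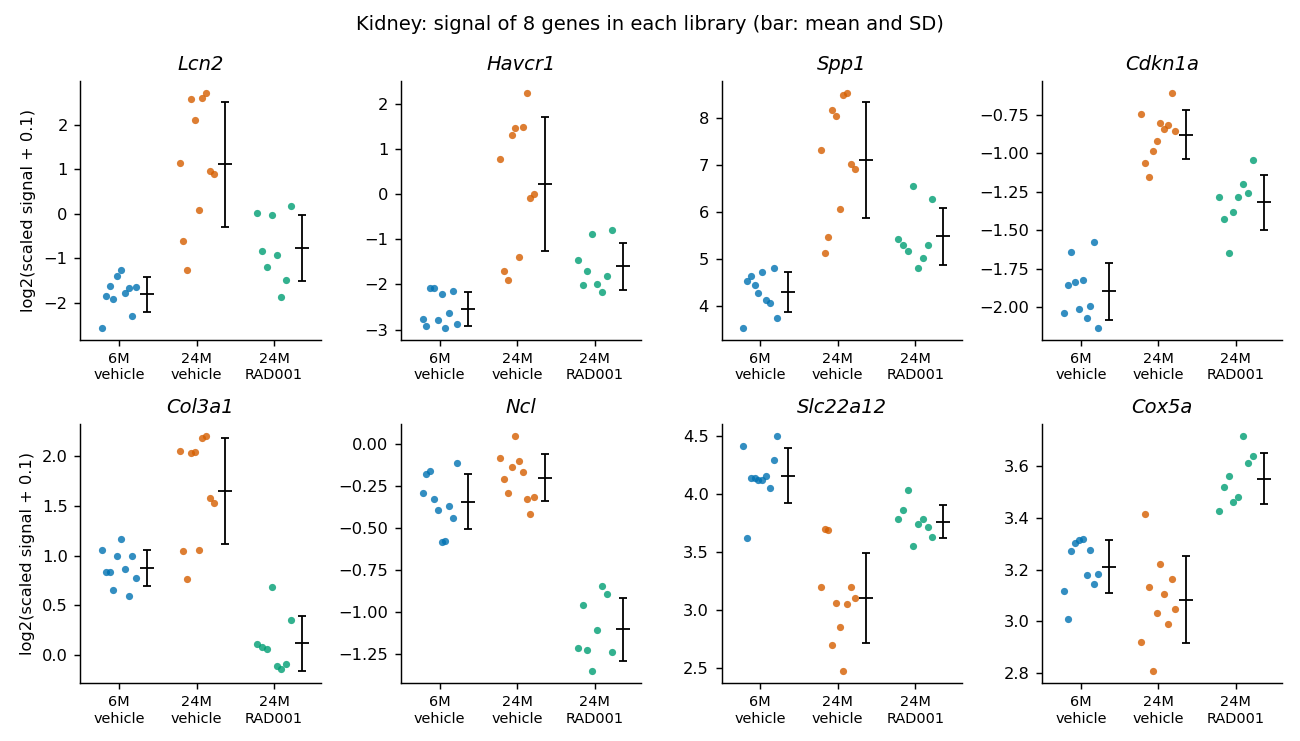
Scaled coverage of kidney genes in each library on the log2(scaled coverage + 0.1) scale, by group (young n = 10, aged n = 10, treated aged n = 8), with points spread sideways in order of replicate number and bars at mean and SD. Lcn2 spans 0.316 to 6.48 in aged and 0.176 to 1.02 in treated aged kidneys, and Ncl spans 0.650 to 0.934 in aged and 0.292 to 0.457 in treated aged kidneys.

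The comparison of treated with untreated aged kidneys asked what mTORC1 inhibition for 6 weeks changed in old animals. Most of these injury markers were lower with treatment. Lcn2 fell from 3.0 ± 2.4 (SD, n = 10) to 0.561 ± 0.329 (SD, n = 8), a log2 change of -1.88 (SE 0.420, adjusted p = 0.00103), Havcr1 changed by -1.82 (SE 0.418) and Spp1 by -1.63 (SE 0.370). Col3a1 (chromosome 9, 51689492 to 51725418) fell from 3.22 ± 1.11 (SD, n = 10) to 1.0 ± 0.234 (SD, n = 8), and Col5a2, a regulator of collagen fibril diameter, fell from 0.880 ± 0.258 (SD, n = 10) to 0.265 ± 0.0478 (SD, n = 8; adjusted p = 1.02e-09). Ncl (chromosome 9, 93097881 to 93106405), the nucleolar protein nucleolin needed for ribosomal RNA transcription, fell from 0.775 ± 0.0846 (SD, n = 10) to 0.369 ± 0.0607 (SD, n = 8), with an adjusted p = 3.79e-10. Some mitochondrial and proximal tubule transcripts rose.

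Of the fibrosis list 23 of 29 genes fell with RAD001 (25 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation). In the tubular injury list 18 of 25 fell (20 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), Cdkn1a among them (log2 change -0.44, adjusted p = 0.000176), while Tff3 rose by 0.96 (adjusted p = 0.00506). Ribosome biogenesis genes fell in 10 of 27 cases (10 adjusted over the list alone; adjusted p = 0.290 with an estimated correlation), and Rrs1, a ribosome assembly factor, had a log2 change of -0.55 (adjusted p = 5.32e-07). The ribosomal RNA transcript Rn5-8s, present in many near-identical copies, fell from 254 ± 127 (SD, n = 10) to 60.0 ± 15.2 (SD, n = 8). These falls stood beside the lower Rn45s and higher 7SL levels of the treated kidneys given above.

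Many immune transcripts fell with RAD001 in kidney. Of 18 macrophage markers 16 fell (16 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), with Trem2 at -0.80 and Csf1r, the receptor that maintains macrophages, at -0.61 on the log2 scale. T cell markers fell in 9 of 14 cases (10 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), including the receptor chain Cd3e (-0.58) and the co-receptor Cd6 (-0.38). With 7SL as a covariate the T cell list was no longer called at the preset correlation (adjusted p = 0.103). In the interferon response list 26 of 32 genes fell (28 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), with the peptide transporter Tap1 at -0.57 and the ADP-ribosyltransferase Parp14 at -0.66. Complement genes fell in 8 of 13 cases (9 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), with C2 at -0.80 and properdin, Cfp, at -0.62. The complement list was no longer called at the preset correlation with upper-quartile scaling (adjusted p = 0.0527) or a value of at least 1 in 8 libraries (adjusted p = 0.323). Mbl1, a mannose-binding lectin of the same list, rose by 0.46 (adjusted p = 0.00918). MHC class II genes fell in 6 of 9 cases (6 lowered and 1 raised adjusted over the list alone; adjusted p = 0.508 with an estimated correlation). Ubd had a log2 change of -3.11 (SE 0.547, adjusted p = 9.73e-05), but its level was under 0.1 in 5 of the 8 treated libraries and between 1.08 and 1.85 in the other 3.

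Of 42 oxidative phosphorylation genes 24 rose (25 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation). Cox5a, a subunit of cytochrome c oxidase, rose from 8.43 ± 1.01 (SD, n = 10) to 11.7 ± 0.815 (SD, n = 8), and Sdhc, a membrane anchor of complex II, by 0.35 (adjusted p = 1.75e-05). Cyc1, the cytochrome of complex III, fell by 0.43 on the log2 scale (adjusted p = 1.45e-05). Fatty acid oxidation genes rose in 9 of 24 cases (10 adjusted over the list alone; adjusted p = 0.508 with an estimated correlation), with Hadhb at 0.30. Among proximal tubule markers 18 of 30 rose (18 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), including the glucose transporter Slc5a2 (SGLT2), from 10.3 ± 1.87 (SD, n = 10) to 15.2 ± 2.43 (SD, n = 8), and Slc22a12 (0.66). Further rises were those of Slc51a, a steroid and bile acid exporter subunit (1.16), Slco1a1 (1.03), the serine protease gene Prss30 (0.98) and Gc, the vitamin D binding protein (0.97). Myc fell by 0.46 on the log2 scale (adjusted p = 0.00189), Mtor rose by 0.25 (adjusted p = 0.0103) and Kl by 0.34 (adjusted p = 0.0415). Gdf15 (-0.11, adjusted p = 0.748) and Nphs1 (0.18, adjusted p = 0.204) did not pass the test.

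With RAD001, 1916 of 10447 genes rose in kidney and 1994 fell. With the upper quartile as factor 33.6% of called genes rose, against 49.0% with the trimmed mean, and the values as deposited gave 39.2% and ended the call of Kl. Of 25 lists 11 were called at the preset correlation, and the smallest adjusted p with an estimated one was 0.290. Because 7SL was higher in the treated kidneys, the fit was also run with the library's 7SL level as a covariate: 441 genes were then called, 418 of them among the 3910 called without it. Of the 3910, 98.5% kept their sign, the median size of the change went from 0.279 to 0.228 and the median SE from 0.0717 to 0.113. Of 46 called genes checked by name 18 were called with the covariate, including Ncl, Rrs1, Col3a1, Col5a2, Cox5a, Cyc1, Rps20 and Rn5-8s. The 28 no longer called included Lcn2, Havcr1, Spp1, Tff3, Cdkn1a, Myc, Mtor, Kl, Ubd, Trem2, Csf1r, Tap1, Parp14, Cd3e, Cd6, C2, Cfp, Gucy1a3, Mbl1, Hadhb, Sdhc, Slc5a2, Slc22a12, Slc51a, Slco1a1, Prss30 and Gc.

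Counter-regulation, named in the title of the series, was examined by crossing both contrasts. Opposite signs do not separate full from partial return to the young level or overshoot. Treated minus young was -0.76 (log2) for kidney Col3a1, an overshoot, and 0.58 for Cdkn1a, a partial return. In kidney, Pigr (chromosome 13, 52652970 to 52680757), which carries IgA across epithelia, rose with age from 2.08 ± 0.421 (SD, n = 10) to 3.83 ± 0.508 (SD, n = 10) and fell with RAD001 to 1.56 ± 0.228 (SD, n = 8). Serping1, the C1 inhibitor, went from 0.914 ± 0.0990 to 1.56 ± 0.400 (SD, n = 10 each) and back to 0.903 ± 0.120 (SD, n = 8). Ahnak, a giant scaffold protein, Pdcd4, a translation inhibitor degraded downstream of S6 kinase, Gucy1a3, a guanylate cyclase subunit, and Rps20 were raised with age by 0.64, 0.40, 0.55 and 0.33 and lowered by RAD001, with log2 changes of -1.01, -0.87, -0.66 and -0.31. In the other direction, Mgll, the lipase of monoacylglycerols, went from 19.9 ± 1.19 to 13.8 ± 2.31 (SD, n = 10 each) and to 21.3 ± 1.33 (SD, n = 8). Cryl1, a crystallin-related dehydrogenase of the glucuronate pathway, Vdac1, the outer mitochondrial membrane channel, Tspan33, a tetraspanin, Ap2a2, a clathrin adaptor subunit, and Pgrmc1, a haem-binding membrane protein, changed with age by -0.53, -0.36, -0.41, -0.44 and -0.37 and rose with RAD001 by 0.56, 0.44, 0.40, 0.42 and 0.50.

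Of the 4492 kidney genes called with age, 2258 (50.3%) were called in the opposite direction with RAD001 and 116 in the same direction. Genes raised with age and lowered by RAD001 numbered 1123, against 415 for independent lists of these sizes, and the reverse numbered 1135, against 425. Both contrasts use the aged vehicle libraries, so the changes correlate negatively by construction. Across genes, which are not independent replicates, Pearson's r was -0.701 and Spearman's rho -0.665. Simulated unchanged groups gave a mean r of -0.568 (SD 0.172), so this r alone does not show a relation beyond the sharing. The covariance was -0.0539, against a simulated mean of -0.00521 (SD 0.00353). With the aged libraries split so that each contrast had its own 5, the median over 21 splits was 1329 opposite (727 to 1542) and 73 same-direction genes (47 to 101). Without shared libraries, r was then -0.631 (-0.675 to -0.516) and the covariance -0.0502 (-0.0531 to -0.0402). Treated aged and young kidneys differed in 2769 genes, 1252 higher and 1517 lower in the treated. With 7SL as a covariate 201 genes were opposite, 30 went the same way and 1073 differed between treated aged and young kidneys.

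**Figure D2:**
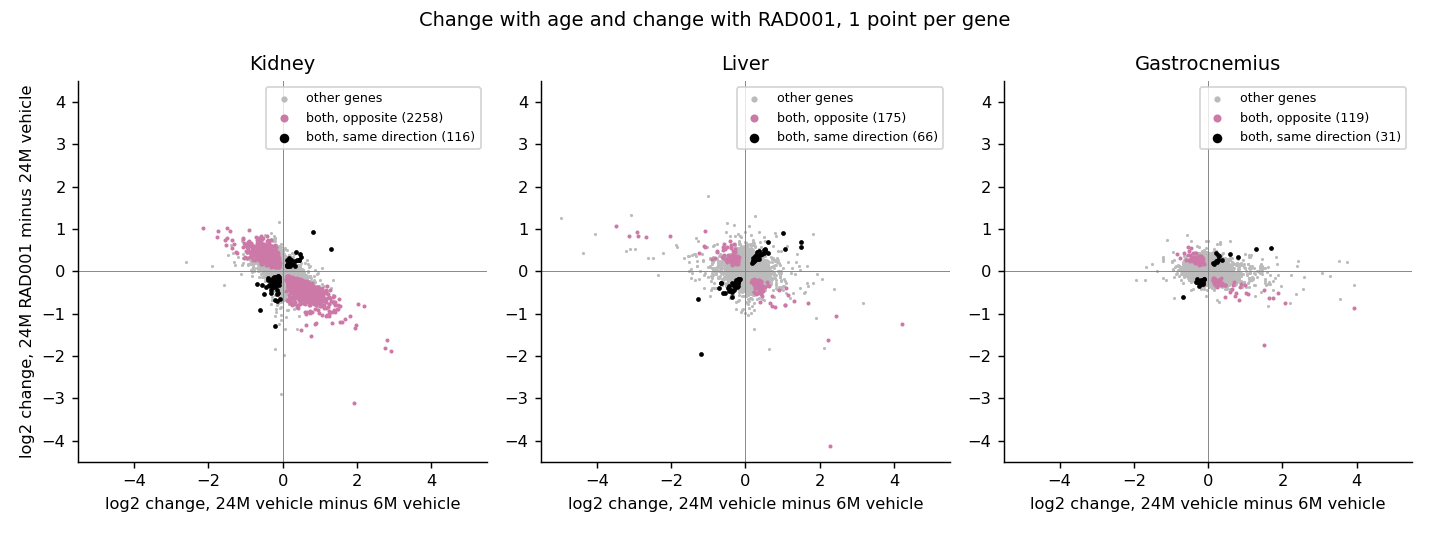
Log2 change with age (horizontal) against log2 change with RAD001 (vertical), 1 point per gene, for kidney, liver and gastrocnemius. Genes called in opposite directions number 2258, 175 and 119 and those called in the same direction 116, 66 and 31.

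In liver, the comparison of aged with young rats asked which hepatic transcripts age had moved. The largest falls among called genes with a mean of at least 1 and a proper name were these. Stac3 (chromosome 7, 70981252 to 70988655), an adaptor of excitation-contraction coupling in muscle, fell from 12.7 ± 3.45 to 0.448 ± 0.538 (SD, n = 10 each), a log2 change of -4.97 (SE 0.434, adjusted p = 1.29e-09). The dehydrogenase Dhrs7 (-4.05), the organic anion transporter Slc22a8 (-3.48), the carbonic anhydrase Car3 (-3.22) and the cadherin Cdh17 (-3.08) followed. Akr1b7 (chromosome 4, 61588010 to 61600050), an aldo-keto reductase, rose from 0.0362 ± 0.0443 to 3.27 ± 3.22 (SD, n = 10 each; adjusted p = 7.29e-10), and the steroid sulfotransferases Sult2a6 and Sult2a2, which have near-identical relatives, rose by 2.44 and 2.22. Ubd rose by 2.27 (SE 0.692) and Rgs16, a brake on G protein signalling, from 0.304 ± 0.442 to 2.30 ± 3.30 (SD, n = 10 each).

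Of 7 measured male-predominant liver genes 6 fell and 1 rose with age, also adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Cyp2c11, the major male-specific cytochrome P450 of rat liver, fell from 118 ± 19.4 to 37.8 ± 18.2 (SD, n = 10 each), and Hao2, a peroxisomal hydroxyacid oxidase, from 36.4 ± 9.73 to 5.89 ± 2.13 (SD, n = 10 each). The member that rose was Cyp4a2, a fatty acid hydroxylase (log2 change 1.81, adjusted p = 0.000666). Female-predominant genes rose in 6 of 10 cases and fell in 3, also adjusted over the list alone (adjusted p = 0.331 with an estimated correlation). Those that fell were the cytochromes Cyp3a9 (-3.13, adjusted p = 9.66e-11) and Cyp2c7 (-0.96, adjusted p = 0.0427) and the flavin monooxygenase Fmo1 (-0.89). Igf1, the growth hormone target of liver, fell from 22.2 ± 2.52 to 14 ± 1.71 (SD, n = 10 each; adjusted p = 7.65e-07). The named members that went against their list's name, here and in the other comparisons, were chosen after their values were seen.

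Among matrix genes in liver 12 of 22 fell with age and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 0.0735 with an estimated correlation). Col3a1 went from 2.71 ± 0.193 to 1.67 ± 0.316 (SD, n = 10 each), the collagen crosslinker Lox changed by -1.52 and Ctgf rose by 0.40 (adjusted p = 0.0158). Macrophage markers rose in 9 of 20 cases (9 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation), with the complement chains C1qa (0.57) and C1qc (0.54). Interferon response genes rose in 9 of 33 cases and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation), including Oasl (0.83) and tetherin, Bst2 (0.57). The member that fell was Ddx58, the RNA sensor RIG-I (-0.26). In the acute phase list 8 of 26 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation). The transcription factor Stat3 rose by 0.81 and the copper carrier ceruloplasmin, Cp, by 0.65. The 2 that fell were Crp (-0.32, adjusted p = 0.000941) and transthyretin, Ttr (-0.32, adjusted p = 0.0276), a protein that falls in the acute phase response.

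Some lipid synthesis genes rose with age in liver. Of 16 fatty acid synthesis genes 5 rose, namely Acss2, Pnpla3, Elovl6, Acaca and Fasn, and Elovl5, an elongase of polyunsaturated fatty acids, fell by 0.61 on the log2 scale (7 and 1 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation). Pnpla3, a lipid droplet protein, rose from 1.97 ± 2.89 to 5.26 ± 3.30 (SD, n = 10 each) and acetyl-CoA synthetase, Acss2, by 0.73. Sterol synthesis had 6 of 23 genes raised (8 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation), with Acat2 at 0.60 and Hsd17b7 at 0.42. In fatty acid oxidation genes such as Acadm and Hadh fell and Ehhadh rose, out of 22 (6 lowered and 2 raised adjusted over the list alone; adjusted p = 0.592 with an estimated correlation). Bile acid genes fell in 8 of 18 cases (9 lowered and 3 raised adjusted over the list alone; adjusted p = 0.0735 with an estimated correlation), with the synthesis enzyme Hsd3b7 at -0.67, and the exporter Abcc3 rose by 1.83 (adjusted p = 1.53e-05). Ribosomal protein genes rose in 13 of 42 cases (16 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation), with Rps6 at 0.29 and Rpl10a at 0.31. The ribosome biogenesis genes Wdr43, Nop2, Nhp2 and Ppan rose, out of 27 (5 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation). The immediate early genes Klf6, Btg2, Zfp36, Junb and Jun rose, out of 10 (6 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation).

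The lysosome list had 7 of 31 genes raised, Gpnmb at 0.91 among them, and Ctsa, the protective protein cathepsin A, lowered by 0.18 on the log2 scale (9 and 1 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation). Of 7 cholangiocyte markers Epcam and Krt18 rose (3 adjusted over the list alone) and of 3 erythroid markers Hbb-b1 rose (3 adjusted over the list alone), both at adjusted p = 0.331 with an estimated correlation. The hepatokine Fgf21 rose by 1.01 (adjusted p = 0.00580). Cdkn1a (0.39, adjusted p = 0.153), Myc (0.43, adjusted p = 0.0692), Gdf15 (0.52, adjusted p = 0.156), Mtor (-0.13, adjusted p = 0.162) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (0.24, adjusted p = 0.781), did not pass the test. In all 707 of 8991 genes rose and 783 fell, and 16 of 25 lists were called at the preset correlation, with a smallest adjusted p of 0.0735 with an estimated one. With the values as deposited 66.6% of called genes rose, against 47.4% with the trimmed mean, and Ctsa, Cyp2c7, Ddx58, Hadh and Ttr lost their call. Without the 9 vehicle libraries whose 7SL level was under 18000, 4 young and 5 aged, 232 genes rose and 283 fell. With a value of at least 1 in 8 libraries the ribosome biogenesis, fatty acid oxidation, interferon response, immediate early and female-predominant lists were no longer called at the preset correlation (adjusted p = 0.135, 0.135, 0.0552, 0.322 and 0.472). Fatty acid oxidation also lost its call with sample quality weights (adjusted p = 0.0717), the female-predominant list with only the 2 groups compared (0.0808) and the cholangiocyte list without a filter (0.150) and with the values as deposited (0.0648). Without the low 7SL libraries the fatty acid synthesis and fatty acid oxidation lists were no longer called at the preset correlation (adjusted p = 0.570 for both), and 35 of 70 called genes checked by name kept their call, Stac3, Dhrs7, Slc22a8, Hao2, Cyp2c11, Akr1b7, Igf1 and Col3a1 among them. Those that lost it included Rgs16, Ubd, Fgf21, Pnpla3, Acss2, Fasn, Cp, Crp, Ttr and Cyp2c7.

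The comparison of treated with untreated aged livers asked for the effect of RAD001 in this organ. Pdk4 (chromosome 4, 30453698 to 30463700), the kinase that shuts glucose oxidation off in fasting, rose from 0.850 ± 0.237 (SD, n = 10) to 2.10 ± 0.889 (SD, n = 8), a log2 change of 1.14 (SE 0.197, adjusted p = 0.000785). Fgf21 (chromosome 1, 102674359 to 102675602), a fasting hormone, rose from 1.19 ± 0.463 (SD, n = 10) to 2.52 ± 1.47 (SD, n = 8), the lipase inhibitor Angptl4 by 1.31, the stress gene Gadd45g by 1.79 and the transcription factor Cebpb by 1.07. Sds, serine dehydratase, which feeds gluconeogenesis, fell from 1.15 ± 0.779 (SD, n = 10) to 0.223 ± 0.261 (SD, n = 8), with an adjusted p = 0.00130. Ubd had a log2 change of -4.14 (SE 0.734, adjusted p = 0.000903), with a level under 0.1 in 5 of the 8 treated libraries and between 3.09 and 3.73 in the other 3.

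Female-predominant genes fell in 4 of 10 cases, namely Akr1b7 (from 3.27 ± 3.22, SD, n = 10, to 1.12 ± 0.741, SD, n = 8), Sult2a2 (log2 change -1.62), Sult2a1 and Trim24, and Cyp3a9 rose by 0.84 (8 and 1 adjusted over the list alone; adjusted p = 0.865 with an estimated correlation). Sult2a6 had a log2 change of -1.05. Of 7 male-predominant genes Hao2 alone rose past the threshold, by 0.81 (1 adjusted over the list alone; adjusted p = 0.865 with an estimated correlation), and Slc22a8 rose by 1.08. Cyp2c11 (log2 change 0.63, adjusted p = 0.140) and Stac3 (1.29 ± 1.20, SD, n = 8, in the treated aged group, adjusted p = 0.0602) did not pass the test. The calls of the male-predominant and female-predominant lists ended with sample quality weights (adjusted p = 0.0754 and 0.0630) and when only the aged groups entered the fit (adjusted p = 0.0860 and 0.0640), and that of the male-predominant list with upper-quartile scaling (adjusted p = 0.0589). In the lysosome list 10 of 31 genes fell (10 adjusted over the list alone; adjusted p = 0.865 with an estimated correlation), with cathepsin L, Ctsl, at -0.40. The autophagy genes Ulk1, the initiating kinase, and Wipi1 rose, by 0.36 and 0.27. The ribosomal protein genes Rpl8 (0.60), Rpl7a (0.45), Rps2 and Rpl6 rose and Rps24 fell by 0.29 on the log2 scale, out of 42 (3 and 1 adjusted over the list alone; adjusted p = 0.865 with an estimated correlation).

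Cdkn1a rose by 0.70 (adjusted p = 0.0173) and Myc by 0.57 (adjusted p = 0.0253) with RAD001 in liver. The changes of Gdf15 (0.72, adjusted p = 0.0563), Cyp7a1 (-1.37, adjusted p = 0.0524), Igf1 (0.07, adjusted p = 0.614) and Mtor (0.04, adjusted p = 0.690) did not pass the test. In all, 685 of 8991 genes rose and 731 fell. The upper quartile as factor put the raised share of calls at 63.3% and the values as deposited, which ended the calls of Rpl6 and Wipi1, at 28.9%, against 48.4% with the trimmed mean, and without aged vehicle library 8 the number lowered was 476. Of 25 lists 4 were called at the preset correlation, and the smallest adjusted p with an estimated one was 0.865. No treated library had a 7SL level under 18000. Without the 9 vehicle libraries that did, 56 genes rose and 67 fell, and of 38 called genes checked by name 7 kept their call, Sds, Rpl8, Ppdpf, Scpep1, Slc9a3r1 and Txndc12 among them. The ribosomal protein list was then no longer called at the preset correlation (adjusted p = 0.232). With sample quality weights neither it nor the lysosome list was called (adjusted p = 0.0630 for both). With 7SL as a covariate 591 genes were called, 568 of them among the 1416 called without it, all 1416 kept their sign, and the median size of the change went from 0.309 to 0.240 and the median SE from 0.0858 to 0.0771. Pdk4, Gadd45g, Cebpb, Sds, Hao2 and Ubd kept their call with the covariate, while Fgf21, Angptl4, Cdkn1a, Myc, Akr1b7, all 3 Sult2a genes, Cyp3a9, Trim24, Rpl6, Rps2, Rps24, Ulk1 and Wipi1 did not.

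For counter-regulation in liver, 175 of the 1490 genes called with age (11.7%) were called in the opposite direction with RAD001 and 66 in the same direction. Raised genes that were lowered numbered 88, against 57.5 for independent lists, and the reverse numbered 87, against 59.7. Scpep1, a serine carboxypeptidase, rose with age to 1.71 ± 0.245 (SD, n = 10) and fell to 1.15 ± 0.193 (SD, n = 8). Dpp4, the incretin-cleaving peptidase, went from 3.05 ± 0.270 to 3.91 ± 0.534 (SD, n = 10 each) and to 2.96 ± 0.262 (SD, n = 8). Slc40a1, the iron exporter ferroportin, the pyruvate dehydrogenase subunit Pdha1, the disulfide reductase Txndc12 and the coactivator Sub1 went the same way, with RAD001 changes of -0.36, -0.31, -0.27 and -0.30. Paqr7, a membrane progestin receptor, fell from 1.57 ± 0.427 to 0.71 ± 0.349 (SD, n = 10 each) and rose to 1.39 ± 0.381 (SD, n = 8). Vtn, the plasma adhesion protein vitronectin, Mreg, Slc9a3r1 and Ppdpf also fell with age and rose with RAD001, by 0.32, 0.57, 0.47 and 0.61.

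Across liver genes r was -0.227 and rho -0.114, and simulated unchanged groups gave a mean r of -0.514 (SD 0.171). The covariance was -0.0139, against a simulated mean of -0.00599 (SD 0.00356). With the aged libraries split between the contrasts, the medians over 21 splits were 37 opposite (15 to 89) and 20 same-direction genes (0 to 308) and a covariance of -0.00864 (-0.0143 to 0.00658). Treated aged and young livers differed in 3142 genes, 1525 higher and 1617 lower in the treated. Without the 9 vehicle libraries of low 7SL, 15 genes were opposite and 1 went the same way. The same-direction count was 43 without young library 5 or treated library 7.

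**Figure D3:**
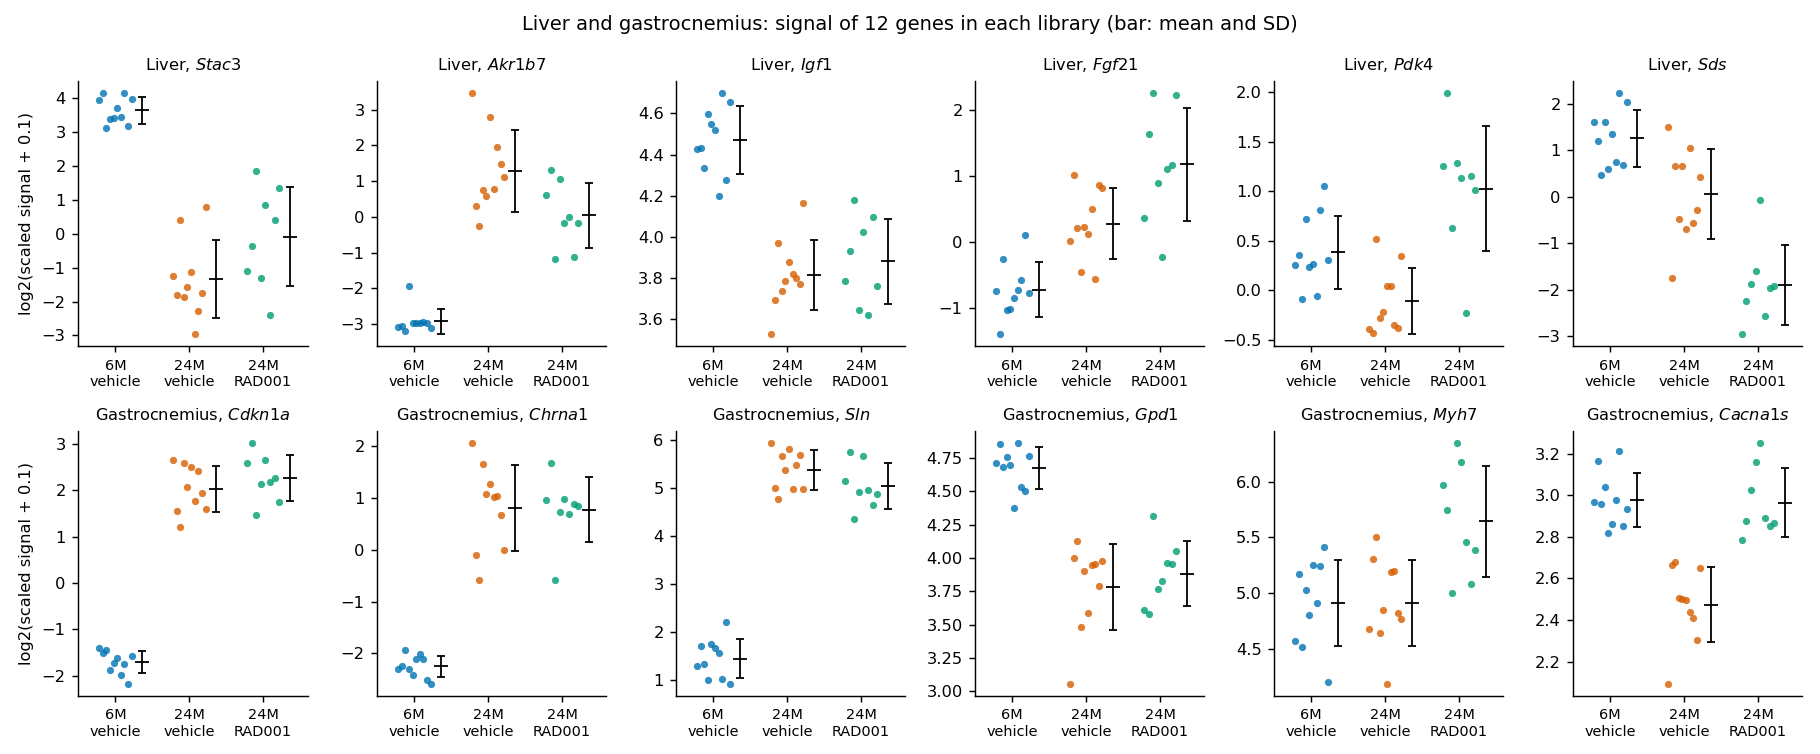
Scaled coverage of 12 genes of liver and gastrocnemius in each library on the log2(scaled coverage + 0.1) scale, by group (young n = 10, aged n = 10, treated aged n = 8), with points spread sideways in order of replicate number and bars at mean and SD. Liver Stac3 spans 8.51 to 17.6 in young and 0.0289 to 1.64 in aged livers, and gastrocnemius Sln spans 1.80 to 4.54 in young and 27.4 to 61.8 in aged muscle.

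In gastrocnemius, a calf muscle of mostly fast fibres, the age comparison asked what distinguished old from young muscle. Sln (chromosome 8, 57012681 to 57016928), sarcolipin, which uncouples the calcium pump of the sarcoplasmic reticulum, rose from 2.73 ± 0.842 to 43.1 ± 12.1 (SD, n = 10 each), a log2 change of 3.93 (SE 0.177, adjusted p = 1.44e-16). Cdkn1a (chromosome 20, 8592437 to 8602879) rose from 0.211 ± 0.0504 to 4.18 ± 1.41 (SD, n = 10 each), with an adjusted p = 1.44e-16. Chrna1 (chromosome 3, 66925893 to 66940958), the acetylcholine receptor subunit that spreads over denervated fibres, rose from 0.112 ± 0.0307 to 1.91 ± 1.08 (SD, n = 10 each), and Myog, the myogenic factor myogenin, from 0.978 ± 0.223 to 5.14 ± 1.65 (SD, n = 10 each). Many fast fibre, glycolytic and mitochondrial genes fell.

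Of 25 denervation and neuromuscular junction genes 21 rose and 2 fell (21 and 2 adjusted over the list alone; adjusted p = 0.0711 with an estimated correlation), with Ankrd1, a stretch-responsive nuclear protein, at 3.27 on the log2 scale. Those that fell were Ache, the acetylcholinesterase of the synapse (-0.41, adjusted p = 0.00123), and Myh8, perinatal myosin (-0.23, adjusted p = 0.0154). In the atrophy list 18 of 27 rose and 2 fell (18 and 2 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). The ubiquitin ligase genes Fbxo30 and Fbxo32 rose by 1.40 and 0.50, while Mstn, which encodes the growth inhibitor myostatin, fell by 0.67 on the log2 scale. Lysosome genes rose in 12 of 31 cases and 1 fell, Lipa, the acid lipase (-0.18) (12 and 1 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation). Cdkn2a, the senescence gene encoding p16, rose from 0.0199 ± 0.0245 to 0.145 ± 0.0595 (SD, n = 10 each), close to the pseudocount.

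Fast fibre genes fell in 15 of 19 cases (15 adjusted over the list alone; adjusted p = 0.190 with an estimated correlation), with phosphofructokinase, Pfkm, from 90.3 ± 9.18 to 53.7 ± 8.99 (SD, n = 10 each) and glycerol phosphate dehydrogenase, Gpd1, at -0.89. In glycolysis 9 of 14 fell (9 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), Pkm at -0.59 among them, and Pgam1, the mutase of non-muscle tissues, rose by 0.31 (adjusted p = 0.000122). Oxidative phosphorylation genes fell in 39 of 42 cases (41 adjusted over the list alone; adjusted p = 0.249 with an estimated correlation), with Ndufb9 at -0.41 and Cox5a at -0.42. Mylk2, the myosin kinase of skeletal muscle (-1.22), Mss51, a mitochondrial regulator of muscle (-1.37), Sema7a, a semaphorin (from 2.42 ± 0.476 to 0.805 ± 0.244, SD, n = 10 each), and Tfrc, the transferrin receptor (-1.93), fell. Matrix genes fell in 11 of 31 cases and 4 rose (11 and 5 adjusted over the list alone; adjusted p = 0.669 with an estimated correlation), with Col3a1 at -0.84 and Col1a2 at -1.21. Among those that rose, Ctgf (0.43), Timp1 (0.42) and Tgfbi (0.24) are a growth factor partner, a metalloproteinase inhibitor and an adhesion protein.

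Some immune genes rose with age in gastrocnemius. Macrophage markers rose in 14 of 18 cases (14 adjusted over the list alone; adjusted p = 0.249 with an estimated correlation), with the Fc receptor Fcgr2b at 0.60 and Laptm5 at 0.40. Of 6 MHC class II genes Cd74 (0.52), RT1-Da (0.62), RT1-Ba, RT1-DMa and RT1-Db1 rose (5 adjusted over the list alone; adjusted p = 0.249 with an estimated correlation). Interferon response genes rose in 9 of 27 cases and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation), with the immunoproteasome subunit Psmb9 at 0.74, Tap1 at 0.55 and Cmpk2, a mitochondrial nucleotide kinase, at -0.25. Of 3 measured T cell markers the co-stimulatory receptor Cd28 rose, by 1.88 (1 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). Immediate early genes rose in 6 of 12 cases, Junb by 1.41 among them, and the nuclear receptor Nr4a1 fell by 0.33 on the log2 scale (7 and 1 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation).

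Ribosomal protein genes rose with age in 29 of 42 cases and 1 fell (32 and 1 adjusted over the list alone; adjusted p = 0.249 with an estimated correlation), with Rpl3 from 3.86 ± 0.280 to 7.24 ± 1.27 (SD, n = 10 each) and Rplp0 at 0.25. The member that fell was Rplp1 (-0.13, adjusted p = 0.0350), which stood at 0.03 with the values as deposited. Ribosome biogenesis genes rose in 13 of 26 cases and Noc4l fell (15 and 1 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation), with the RNA polymerase I subunit Polr1a at 0.37 and the snoRNP protein Nhp2 at 0.28. Other large rises among called genes with a mean of at least 1 were those of Ctxn3, a small membrane protein (3.93), the kallikrein Klk1c7, which has near-identical relatives (3.56), and Tmem158, a Ras-induced membrane protein (3.51). Mtor (-0.01, adjusted p = 0.949) and the slow myosin Myh7 (0.00, adjusted p = 0.994) did not pass the test. In all 1502 of 8836 genes rose and 1628 fell, and 14 of 25 lists were called at the preset correlation, with a smallest adjusted p of 0.0711 with an estimated one. The fibrosis list was no longer called with a value of at least 1 in 8 libraries (adjusted p = 0.0747). With the values as deposited, which shift the median of all genes by 0.128, 2567 genes rose and 423 fell, a raised share of 85.9% against 48.0% with the trimmed mean, and Myh8, Lipa, Cmpk2, Nr4a1, Noc4l, Synm, Trdn and Fam160b2 lost their call.

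The comparison of treated with untreated aged muscle asked for the effect of RAD001 there. Cacna1s (chromosome 13, 57945479 to 58018760), the voltage sensor of excitation-contraction coupling, rose from 5.49 ± 0.666 (SD, n = 10) to 7.75 ± 0.939 (SD, n = 8), a log2 change of 0.49 (SE 0.0729, adjusted p = 0.000363). Myh7 (chromosome 15, 37521021 to 37542688) rose from 31 ± 8.12 (SD, n = 10) to 52.6 ± 18.1 (SD, n = 8), and its neighbour and close homologue Myh6 by 0.71. Ctxn3 fell from 3.01 ± 1.21 (SD, n = 10) to 1.55 ± 0.565 (SD, n = 8) and the glutathione transferase Gstm2, of a family of near-identical genes, from 9.94 ± 1.08 (SD, n = 10) to 7.25 ± 0.843 (SD, n = 8). Cilp, a cartilage matrix protein, rose by 0.56 and the cytoskeletal linker Plec by 0.51. The protease inhibitor Cst7 (-0.76), Gsta1 (-0.64), Cdkn2a (-0.50) and Fhl3, a LIM protein (-0.42), fell.

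Of 18 slow fibre genes Myh7 and Myh6 rose (7 adjusted over the list alone; adjusted p = 0.870 with an estimated correlation). In the interferon response list 0 of 27 genes passed the threshold in limma, with 7 at an unadjusted p under 0.05 (3 fell adjusted over the list alone; adjusted p = 0.870 with an estimated correlation), and of 42 ribosomal protein genes Rpl3 fell by 0.29 on the log2 scale (0 adjusted over the list alone; adjusted p = 0.870 with an estimated correlation). Neither Chrna1 (-0.04, adjusted p = 0.955), Myog (-0.09, adjusted p = 0.802), Fbxo32 (-0.02, adjusted p = 0.958), Cdkn1a (0.23, adjusted p = 0.49) nor Mtor (0.21, adjusted p = 0.104) passed the test. In all 152 of 8836 genes rose and 146 fell, and 3 of 25 lists were called at the preset correlation, with a smallest adjusted p of 0.870 with an estimated one. With the values as deposited 1 gene rose and 10 fell, and of 21 called genes checked by name Cacna1s, Ctxn3 and Gstm2 kept their call. Leaving out 1 library gave 63 to 190 raised and 95 to 188 lowered. With 7SL as a covariate 164 genes were called, 158 of them among the 298, and Myh7, Myh6, Plec and Rpl3 were not. All 298 kept their sign, the median size of the change went from 0.275 to 0.255 and the median SE stayed at 0.067. The ribosomal protein list was then no longer called (adjusted p = 0.251), nor with a value of at least 1 in 8 libraries (adjusted p = 0.0831).

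For counter-regulation in gastrocnemius, 119 of the 3130 genes called with age (3.80%) were called in the opposite direction with RAD001 and 31 in the same direction. Raised genes that were lowered numbered 67, against 24.8 for independent lists, and the reverse numbered 52, against 28. Cacna1s, at 7.75 ± 0.939 (SD, n = 8) in the treated aged group, had stood at 7.81 ± 0.731 (SD, n = 10) in the young. Myf6, the myogenic factor MRF4, went from 4.88 ± 0.617 to 7.76 ± 1.38 (SD, n = 10 each) and to 5.76 ± 0.411 (SD, n = 8). The proteasome subunits Psma1 and Psmb4 and the copper-handling protein Commd1 rose with age by 0.25, 0.18 and 0.22 and fell with RAD001 by 0.27, 0.28 and 0.25 on the log2 scale. Synm, the intermediate filament synemin, Zfand3, Tuba8, a tubulin, Trdn, the junctional protein triadin, and Fam160b2 fell with age and rose with RAD001, by 0.43, 0.34, 0.42, 0.22 and 0.30.

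Across gastrocnemius genes r was -0.224 and rho -0.201, with a mean r of -0.463 (SD 0.159) in simulated unchanged groups. The covariance was -0.00880, against a simulated mean of -0.00365 (SD 0.00210). With the aged libraries split, the medians over 21 splits were 11 opposite (3 to 89) and 7 same-direction genes (0 to 34) and a covariance of -0.00441 (-0.0124 to 0.00313). Treated aged and young muscle differed in 3227 genes. Leaving out 1 library gave 71 to 162 opposite and 13 to 46 same-direction genes.

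**Figure D4:**
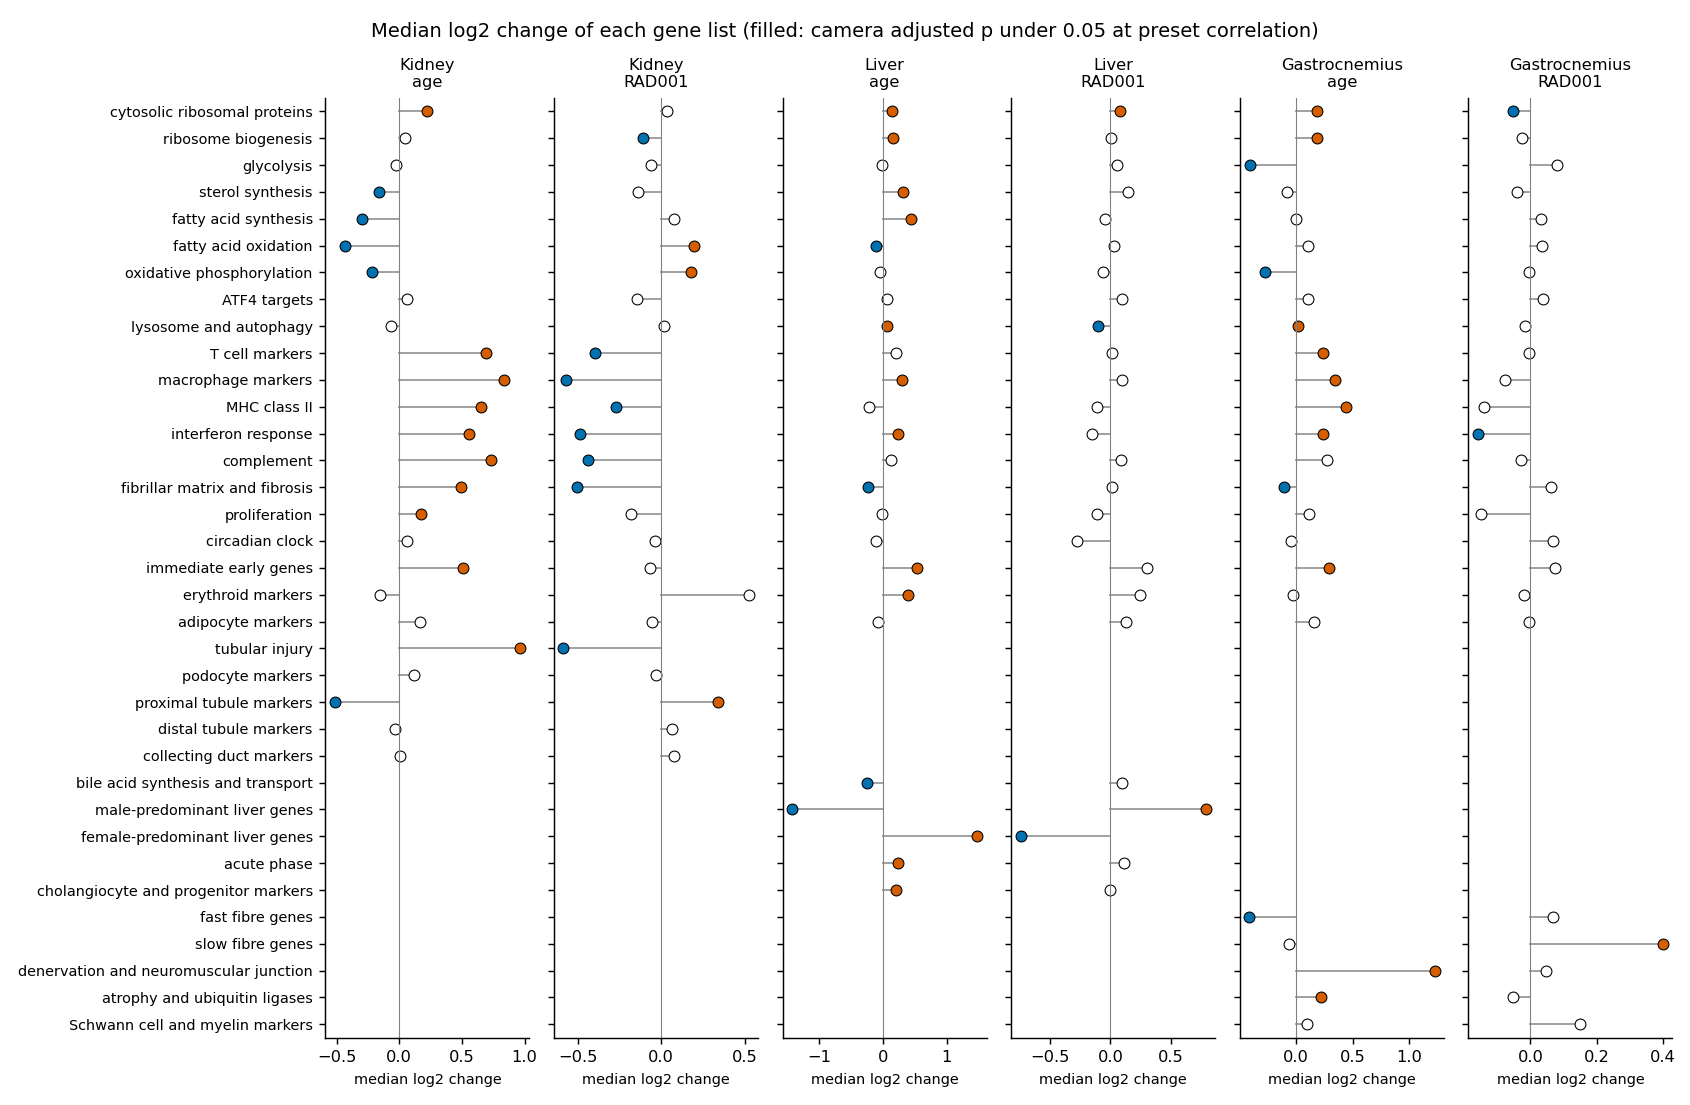
Median log2 change of the measured members of each list, fixed before the data were examined, with age and with RAD001 in each tissue; filled points passed camera at the preset correlation. The panels have different horizontal scales, and no list passed with an estimated correlation.

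Joint limma fits with libraries as independent tested tissue differences by interaction terms. The age change differed between kidney and liver in 2076 of 8576 genes, between kidney and gastrocnemius in 2884 of 8342 and between liver and gastrocnemius in 1724 of 7695. For the RAD001 change the counts were 2312, 2358 and 334. Dhrs7 fell with age in kidney and more in liver, a difference of 2.55 (SE 0.459, adjusted p = 3.21e-05). Cdkn1a rose by 1.02 with age in kidney and by 3.73 in gastrocnemius, a difference of -2.71 (SE 0.196, adjusted p = 9.43e-16). With RAD001, Cdkn1a and Myc fell in kidney and rose in liver. The differences were -1.14 (SE 0.219, adjusted p = 0.000109) and -1.02 (SE 0.208, adjusted p = 0.000224). In kidney and in liver these Cdkn1a and Myc calls with RAD001 ended with 7SL as a covariate. Genes called with age in all 3 tissues numbered 85 raised and 57 lowered among 7647. With RAD001, Ube2m, Itgb5, Zfand3, Pnrc1, Aes and Tuba4a rose and Gusb, Ctsl, Ubd, Vps26a and Pdia6 fell in all 3 tissues, named after their values were seen.

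**Figure D5:**
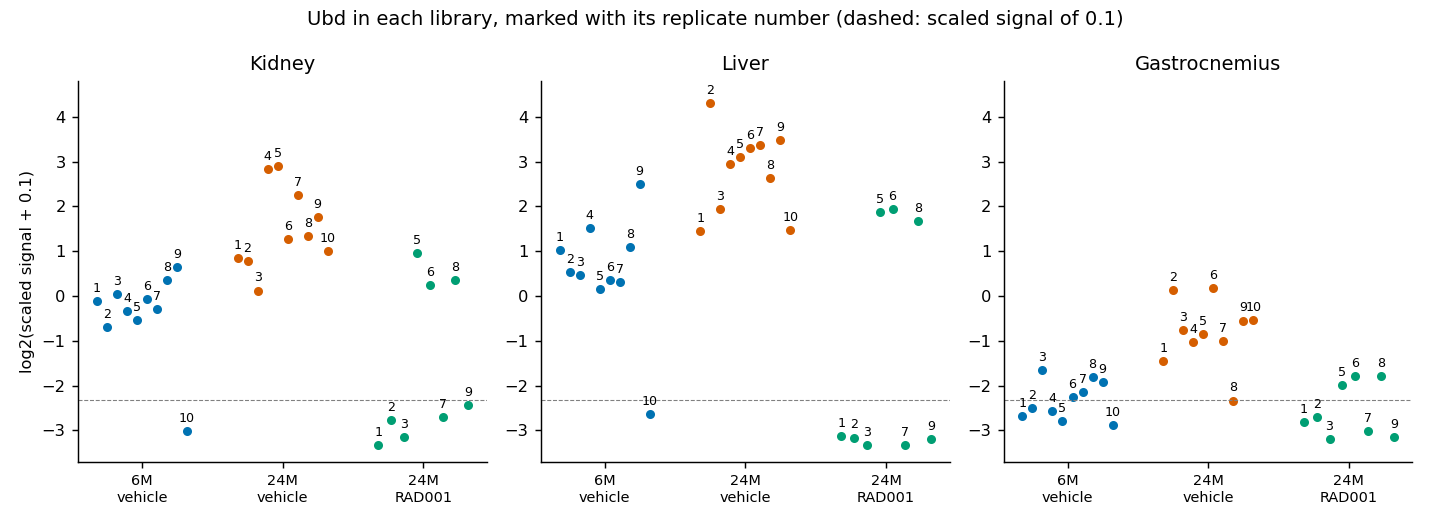
Ubd in each library of kidney, liver and gastrocnemius on the log2(scaled coverage + 0.1) scale, each point marked with its replicate number, with a dashed line at a scaled coverage of 0.1. In all 3 tissues treated libraries 1, 2, 3, 7 and 9 and young library 10 lie below the line.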

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

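The tests of a variant of single rats and of lowering in every treated rat for Ubd and of 7SL for the kidney ribosome biogenesis list were chosen only after the result was seen. The other tests weighed here were written before their result was seen. The values below are scaled coverage of libraries far from the rest of their group by Dixon's rule. It was met in 41 of 702 groups tested, in 27 libraries, while chance alone gives 35.1.

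In kidney these were Ubd in young library 10 (0.0233), Rpl3 and Nphs1 in young library 1 (18.7 and 0.444), Slc22a12, Ahnak and Pdcd4 in young library 2 (12.2, 5.83 and 2.19), Cd3d and Rrs1 in young library 3 (0.145 and 0.423), Rps20 in aged library 9 (6.32), Tff3 and Gucy1b2 in treated library 7 (40.3 and 0.791) and Mbl1 in treated library 5 (1.24). In liver they were Akr1b7 and Rpl7a in young library 4 (0.161 and 0.296), Sult2a6, Lox and Ubd in young library 10 (0.978, 1.08 and 0.0605), Slc22a8, Ctsa, Elovl6 and Hadh in young library 2 (0.645, 6.92, 0.786 and 11.8), C1qc in young library 1 (4.36), Abcc3 in young library 9 (0.417), Nhp2 in young library 8 (0.75), Gpnmb in aged library 2 (0.808), Sds in treated library 6 (0.850) and Hbb-b1 in treated library 9 (11.8). In gastrocnemius they were Col1a2 and Psma1 in young library 4 (11.1 and 3.45), Fcgr2b in young library 10 (0.0599), Gsta1 in young library 9 (6.94), Rplp1 and Gpnmb in young library 8 (66.0 and 0.477), Noc4l in young library 2 (0.165) and aged library 5 (0.146), Ctxn3 and Ache in treated library 2 (2.86 and 0.577), Chrna1 in treated library 3 (0.565), Cmpk2 in treated library 5 (0.0808), Mstn in treated library 1 (0.591) and Commd1 in treated library 7 (1.75).

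Differences between tissues that passed the interaction test were, for age, Dhrs7 in kidney minus liver (2.55, adjusted p = 3.21e-05, lower in 10 of 10 aged libraries of each tissue) and Cdkn1a in kidney minus liver (0.63, adjusted p = 0.0201, higher in 10 and 7 of 10). Cdkn1a in kidney minus gastrocnemius was -2.71 (adjusted p = 9.43e-16, higher in 10 and 10 of 10) and in liver minus gastrocnemius -3.34 (adjusted p = 5.62e-15, higher in 7 and 10 of 10). Rpl3 in kidney minus gastrocnemius was -0.53 (adjusted p = 2.16e-05, higher in 10 and 10 of 10). For RAD001 they were Cdkn1a in kidney minus liver (-1.14, adjusted p = 0.000109, 8 and 8 of 8 in the direction of their tissue's change), Myc in kidney minus liver (-1.02, adjusted p = 0.000224, 8 and 7 of 8) and Cdkn1a in kidney minus gastrocnemius (-0.67, adjusted p = 0.0124, 8 and 6 of 8).

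Ubd lay under 0.1 in all 3 tissues in treated libraries 1, 2, 3, 7 and 9 and in young library 10, which is 5 of 8 treated and 0 of 10 aged vehicle numbers. Libraries of another group under the RAD001 label stay open. Of these kidneys 5 of 5 lay closest to the other RAD001 kidneys, whose mean they help form. Lowering in every treated rat stays open, since 3 of 3 treated libraries not near 0 lay inside the aged vehicle range (1.08 to 1.85 within 0.989 to 7.40 in kidney, 3.09 to 3.73 within 2.64 to 19.7 in liver), which does not forbid it. A variant of single rats, unevenly spread over the groups, cannot be told apart from an effect of treatment in some or all rats: deviations of Ubd correlated between same-numbered libraries, but the lowest r, 0.465 for kidney and gastrocnemius, missed the 0.5 stated for it, muscle levels lie near the floor, and no genotype was analysed here. The correlations (family of 3) were r 0.869 (permutation p = 9e-05, rho 0.795 with p = 0.00016, r 0.812 without the 2 farthest, adjusted p = 0.00027) for kidney and liver, 0.465 (0.0154, 0.511 with 0.0116, 0.396, 0.0154) for kidney and gastrocnemius, and 0.622 (0.00052, 0.678 with 0.00036, 0.561, 0.00078) for liver and gastrocnemius.

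In kidney, 849 genes (369 raised, 480 lowered, 21.7% of RAD001 calls) set the treated libraries apart from both vehicle groups. For 848 of them the change predicted from slopes within the vehicle groups correlated with the RAD001 change at r -0.105 for sequencing depth, -0.299 for Rn45s and 0.306 for 7SL, each within the range of 100 shuffles, so these sources cannot be told apart from an effect of RAD001. With Rn45s as a covariate the mean change of the ribosome biogenesis genes was -0.232 (SE 0.0480), against -0.168 (SE 0.0217) without it. With 7SL as a covariate it was -0.147 (SE 0.0350). These values argue against a linear effect of either measure as the whole cause. Both measures differ between treated and untreated aged kidneys, so the fits rest on slopes within groups and cannot exclude either. Lower ribosome production under mTORC1 inhibition is a candidate explanation that stays open beside depth and library composition for kidney. Against it, Rn45s was higher in treated than in untreated aged liver (417 against 334) and gastrocnemius (280 against 247).

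In liver, the changes with RAD001 followed 7SL: slopes on 7SL within the vehicle groups predicted them at r 0.755, with 0 of 100 shuffles as high (highest 0.743) and a median predicted share of 0.206 of the change. This is consistent with a part of the liver RAD001 calls coming from library composition. Depth, at r 0.550 with 11 of 100 shuffles as high, cannot be told apart from it. An effect of RAD001 stays open for the rest.

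Other splits of the same libraries, 100 per count with the real one included, tested whether relabelled libraries give as many genes. In each case 1 split, the real one, did, so none of the other splits drawn reached the real count. For the opposite counts all 3 groups were relabelled, which also removes the age and RAD001 changes. Those counts therefore do not test what the shared aged vehicle libraries alone give. Real and highest other counts were 4492 and 2977 (age), 3910 and 1530 (RAD001), 2769 and 3 (treated aged against young) and 2258 and 730 (opposite) in kidney. They were 1490 and 124, 1416 and 23, 3142 and 240, and 175 and 0 in liver. In gastrocnemius they were 3130 and 1421, 298 and 126, 3227 and 152, and 119 and 0.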

How the results depend on the processing

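The settings chosen only after the data were seen are sample quality weights, both other pseudocounts, values as deposited, the odd or even number term, the 7SL covariate and liver without libraries of low 7SL, as was the test by shuffled numberings. Over all settings except leaving out libraries, results for named genes kept direction and side of the threshold in 3985 cases, lost the call in 416, gained it in 16 and reversed in 7. List results did so in 1854, 90 and 36 cases, and none reversed. Among correlations and covariances 77 held and 3 moved. Leaving out each library in turn moved a count over 1.5 times in 19 cases. Unless a cause is named, the cause was not tested.

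Of the results that reversed, Rplp1 was the one past the threshold in the main setting. They were Cyp7a1 with age in liver (0.24) at -7.35e-05 with quality weights and -0.18 without libraries of low 7SL; Fbxo32 with RAD001 in gastrocnemius (-0.02) at 0.00044 with a value of at least 1 in 8 libraries and 0.0079 with the replicate block. In gastrocnemius with age, Mtor stood at 0.13 and Rplp1 (-0.13) at 0.0276 with the values as deposited, and Myh7 at -0.0113 with the 7SL covariate.

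With 7SL as a covariate, kidney had 168 genes raised and 273 lowered by RAD001, 1073 differing between treated aged and young, 201 opposite and 30 the same way. Liver had 293 raised and 298 lowered by RAD001 and 34 the same way, and gastrocnemius 74, 90, 71 opposite and 19 the same way. The kidney correlation of changes moved to -0.56. The kidney covariance moved to -0.0845 at pseudocount 0.01 and to -0.0262 at 0.5. Without libraries of low 7SL liver had 232 raised and 283 lowered with age, 56 and 67 with RAD001, 1744 differing, 15 opposite and 1 the same way, with 9 fewer libraries in the fit.

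At an adjusted p under 0.01, stricter by construction, kidney had 1151 raised and 1161 lowered by RAD001, 1542 differing, 1218 opposite and 37 the same way. Liver had 328 and 395 with age, 145 and 142 with RAD001, 1832, 29 and 1. Gastrocnemius had 24 and 30 with RAD001, 19 and 5. With at least 1.5-fold, also stricter by construction, kidney had 458 and 213 with age, 81 and 246 with RAD001, 201 differing, 192 opposite and 2 the same way. Liver had 139, 151, 45, 39, 415, 19 and 5 in that order, and gastrocnemius 243, 80, 3, 8, 336, 6 and 1.

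With a value of at least 1 in 8 libraries fewer genes are tested by construction: kidney had 1061 and 1089 with age, 954 and 989 with RAD001, 1672 differing and 1037 opposite. Liver had 388, 413, 362, 380 and 1414 differing, and gastrocnemius 812 and 827 with age and 1591 differing. Without a filter gastrocnemius had 92 raised by RAD001 and 17 the same way. With the values as deposited kidney had 1418 lowered with age, 1188 raised by RAD001 and 42 the same way; liver had 486 lowered with age and 451 and 1107 with RAD001. Gastrocnemius then had 2567 and 423 with age, 1 and 10 with RAD001, 8 opposite and 1 the same way. With the aged vehicle libraries split between the contrasts, fewer per contrast by construction, the medians were 1329, 37 and 11 opposite and 73, 20 and 7 the same way in kidney, liver and gastrocnemius.

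Leaving out 1 library gave these lowest and highest counts. Liver: lowered by RAD001 476 (without aged 8) to 900 and the same way 43 (without young 5 or treated 7) to 77. Gastrocnemius: raised by RAD001 63 to 190 (63, 65, 88, 91 and 95 without treated 5, treated 6, aged 7, treated 1 and aged 1), lowered 95 (without treated 6) to 188, opposite 71 to 162 (71, 71 and 77 without aged 1, treated 5 and treated 6) and the same way 13 to 46 (13, 17, 18, 18, 19, 20 and 20 without treated 6, aged 7, treated 1, treated 5, aged 10, aged 3 and treated 7).

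Replicate numbers were not taken to pair libraries across groups, since the labels do not say so and correlations of same-numbered libraries passed 0.1 in at most 6 of 10 pairs (young and aged liver). In kidney, liver and gastrocnemius 5, 5 and 8 of 28 libraries lay closest to their own number, against means of 2.7, 2.55 and 2.55 and highest counts of 9, 7 and 6 over 100 shuffled numberings, so in gastrocnemius the numbers share something not identified here. As a block they gave 2131 and 2279 with age and 1751 and 1804 with RAD001 in kidney, 758, 838, 586 and 565 in liver and 1501, 1645, 118 and 132 in gastrocnemius, none moved over 1.5 times. As a random block in the joint fits they gave 2351, 2976 and 1809 differences with age and 2640, 2513 and 434 with RAD001, in the order above.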

Other observations

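The tests of the interferon level shared by tissues, of the spread of the injury level, of the same number in 2 tissues and of the injury level against other lists were chosen only after the result was seen. In liver, the immediate early gene Jun rose with RAD001 by 0.70 (adjusted p = 0.0249). In gastrocnemius, Mstn, which encodes myostatin, fell with RAD001 by 0.59 on the log2 scale (adjusted p = 0.00777) after a fall with age, Cd28 fell by 0.52 (adjusted p = 0.0424) and Ctsl by 0.33 (adjusted p = 0.0482). Between treated aged and young rats, Cyc1 in kidney differed by -0.60 (adjusted p = 6.42e-08) and Cyp4a2 in liver by 2.70 (adjusted p = 6.59e-06). These genes were chosen after their values were seen.

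Libraries of the same number within a group may come from the same rat. Deviations from group means correlated between same-numbered libraries at a mean r of 0.155 for kidney and liver, 0.0669 for kidney and gastrocnemius and 0.0753 for liver and gastrocnemius, with 0 of 100 shuffled numberings as high in each. The labels do not state it.

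The mean level of the interferon response list may reflect a state or variant of the rat shared by its tissues. With group means removed it correlated between same-numbered kidney and liver libraries at r 0.673 (0.570 in young, 0.795 in aged and 0.134 in treated aged libraries) (permutation p = 0.00484, rho 0.418 with p = 0.0358, adjusted p = 0.0110 in a family of 7), but r was 0.223 without the 2 farthest libraries, so it rests on those, and the treated group shows little of it. For kidney and gastrocnemius r was 0.622 (0.661, 0.751 and -0.232 in the same groups; p = 0.0211, rho 0.333 with p = 0.0931, 0.165 without the 2 farthest, adjusted p = 0.0211). For liver and gastrocnemius it was 0.895 (0.660, 0.956 and 0.802; p = 1e-05, the smallest that 100000 permutations can give, rho 0.742 with p = 2e-05, 0.703 without the 2 farthest, adjusted p = 7e-05).

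RNA of infiltrating T cells and macrophages is a candidate source of the interferon level of single kidneys. With group means removed it correlated with the macrophage list at r 0.628 (0.31 in young, 0.63 in aged and 0.77 in treated aged kidneys) (p = 0.00735, rho 0.764 with p = 1e-04, 0.805 without the 2 farthest, adjusted p = 0.0110) and with the T cell list at 0.608 (0.30, 0.63 and 0.68; p = 0.00783, rho 0.756 with p = 0.00013, 0.729, adjusted p = 0.0110). Tissue cells express interferon response genes as well, and correlation does not separate these sources. The tubular injury level correlated with the macrophage list at r 0.872 (-0.0101, 0.923 and 0.882, so not in young kidneys; p = 2e-05, rho 0.811 with p = 7e-05, 0.875, adjusted p = 7e-05) and with oxidative phosphorylation at -0.614 (0.683, -0.763 and -0.433, so the other way in young kidneys; p = 0.0148, rho -0.452 with p = 0.0407, -0.461, adjusted p = 0.0173).

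Treated aged kidneys may vary less in tubular injury than untreated ones: the mean distance from the group median was 0.465 in aged, 0.167 in treated aged and 0.0862 in young kidneys, a difference of 0.298 between the aged groups (permutation p = 0.0205). The lower level of the list in treated kidneys and a smaller spread go together here and were not tested apart.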
